A study of Oryza sativa with 14 samples.

How the data were processed

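Rice (japonica cultivar Zhonghua 11) was grown in a phytotron, and total RNA from ovary, embryo and endosperm was hybridized to the Affymetrix Rice Genome array, per the labels. The 14 arrays form 7 groups of 2 arrays labelled as biological repeats: ovary at flowering, embryo at 3, 9 and 12 days after flowering (DAF), and endosperm at 3, 9 and 16 DAF. Ovary replicate 2 carries a description with a later day than its stage label, and it was kept with the ovary group by title and tissue. The labels do not say how embryo and endosperm were separated. No method other than expression arrays was used here.

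The deposited values are linear signal intensities made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The mean of the middle 96% of probe sets lay at about 500 on every array, so the deposited intensities were already scaled per array. The array medians ran from 40.2 to 76.1 and the brightest values from 34690 to 175700. Of 57381 probe sets, 123 are array controls and were left out of the tests. In the gene table, 22436 of the other probe sets carry 1 gene symbol, 95 carry several and 34727 carry none. Probe sets with several symbols or none were tested and counted but were not named. The table covers 17905 genes, of which 2453 have a name other than a locus number or clone name; it holds no descriptions and no locus numbers of the public rice annotation.

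Values were taken as log2(value + 12.0), where 12.0 is the 25th percentile of all values. A probe set was kept when it exceeded its array's median on at least 2 of the 14 arrays, which left 39864 probe sets and removed 17394. The kept probe sets cover 16889 genes, 2347 of them named. A gene is represented by its brightest probe set. All 14 arrays entered a single limma model with 7 group means, no block, and eBayes moderation (residual degrees of freedom 7, prior degrees of freedom 4.85). A call means a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The number of arrays limits precision to n = 2 per group. Recovery of known changes was measured in simulated data of the same design. The changed probe sets were drawn only above a minimum intensity, so the rates do not cover dimmer probe sets. Log2 changes of 4 were called for 86 to 100% of 50 changed probe sets per comparison. Changes of 3 were called for 68 to 86%, of 2 for 8 to 20% and of 1 for 0 to 2%; of unchanged probe sets, 2 to 9 were called.

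There were 8 pairwise comparisons: embryo against endosperm at 3 and at 9 DAF, embryo at 9 against 3 and at 12 against 9 DAF, endosperm at 9 against 3 and at 16 against 9 DAF, and embryo and endosperm at 3 DAF each against ovary. The tissue by time interaction tested whether the change from 3 to 9 DAF differs between embryo and endosperm. The probe sets called in both ovary comparisons were compared with 100 simulated data sets that share the ovary arrays and hold no change.

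Lists of genes were tested with camera from limma at its preset correlation of 0.01, and again with the correlation estimated for each list. The p values of each were adjusted over all 162 tests. The 22 lists cover starch synthesis, sucrose import and cleavage, endosperm storage proteins, endosperm transcription factors, protein folding in the endoplasmic reticulum (ER), late embryogenesis abundant proteins, oil bodies, embryo maturation regulators, embryo patterning and meristem, cell cycle and DNA replication, histones, cytosolic ribosomal proteins, floral organ MADS-box genes, photosynthesis, lipid transfer proteins, auxin, gibberellin, cytokinin, abscisic acid, heat shock proteins, expansins and cellulose synthesis, and Polycomb and imprinted genes. Members were matched by symbol and synonym, because the gene table has no descriptions; the matching patterns were written after the symbols were seen. The floral MADS-box list was chosen as markers of ovary and maternal tissue, and the photosynthesis list as markers of green pericarp. The 18 lists with at least 3 measured members were tested. In simulated data limma camera passed a shifted list of 20 genes and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this does not show how the preset correlation performs on correlated lists.

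Genes named in the report were picked by rule. They are the 5 called named genes with the largest change each way whose arrays did not overlap, up to 3 called members each way per list, and a panel of 28 seed genes. For 15 panel genes a probe set was measured. The others were not used here: AGPL2, BEIIb, BT1, GluB1, RPBF, RISBZ1, NAC26, OLE16, LEC1 and FIE1 matched no symbol, and ISA1, OLE18 and OSH15 had no probe set of their own.

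The groups, the model, the thresholds, the panel, the comparisons, the list topics and most alternatives were chosen before the data were examined. Those alternatives were quantile normalization, scaling to the 75th percentile, no pseudocount or the median as pseudocount, no filter or a filter at the 75th percentile, no minimum fold change, a stricter threshold, the mean of all probe sets of a gene, a variance trend, a fit of only the compared groups, a replicate block, the estimated list correlation, and each array left out in turn. Chosen after the data were seen were scaling to the 9 hybridization controls, leaving out the 2 arrays with the highest 3' to 5' ratios of the control genes, and dividing the 2 ovary arrays between the embryo and endosperm comparisons. Replicate numbers carry no order, and no day, batch or litter is given for them. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.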

Results

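The glutelin gene GluA2 averaged 66.2 in ovary, 11490 in embryo and 47890 in endosperm at 3 DAF, and 123200 ± 10200 (SD, n = 2) in endosperm at 16 DAF. The meristem homeobox gene OSH1 averaged 2570 in ovary and 2697 in embryo at 3 DAF, against 41.6 in endosperm of the same day. MFT2, a member of the MOTHER OF FT family, averaged 12.9 in ovary, 18430 in embryo at 3 DAF and 10970 ± 9500 (SD, n = 2) in endosperm at 16 DAF. Levels are deposited intensities as mean ± SD of n = 2 arrays. Fold changes are limma estimates with SE on the log2(value + 12.0) scale, which understates the changes of genes of low intensity. Where a level lies below 12.0 the pseudocount sets the size of the fold change.

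The 6 endosperm arrays lay apart from the embryo and ovary arrays on the principal component with 38.4% of the variance, and the ovary arrays lay apart on the next, with 19.1%. Replicate arrays correlated from 0.878 (endosperm at 16 DAF) to 0.949 (embryo at 9 DAF). The actin control had a 3' to 5' ratio of 1388 on embryo at 3 DAF replicate 1 against 16.2 on replicate 2, and of 948 on endosperm at 16 DAF replicate 2 against 25.2 on replicate 1. It was 59.5 and 99.5 on the ovary arrays, 140 and 66.3 on endosperm at 3 DAF, 25.9 and 20.7 on endosperm at 9 DAF, and 5.16 to 6.34 on embryo at 9 and 12 DAF. The hybridization controls averaged 12660 and 16610 on the endosperm arrays at 16 DAF and 1636 to 6292 on the other 12 arrays.

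**Figure D1:**
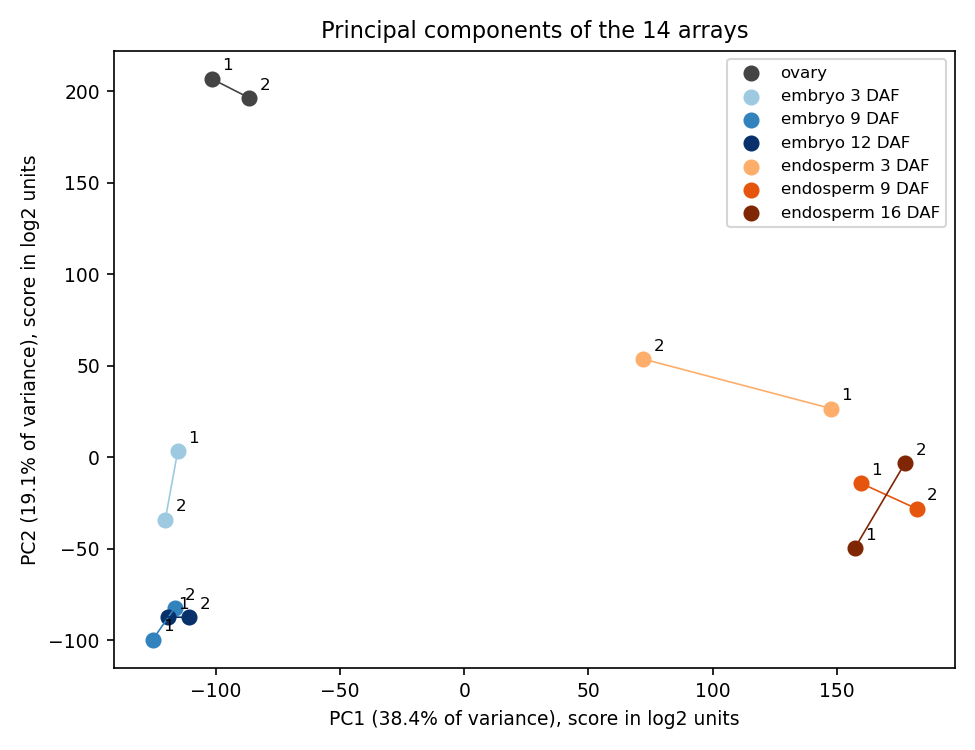
Scores of the 14 arrays (points, numbered by replicate and colored by group, 2 per group, joined by a line) on the components with 38.4% and 19.1% of the variance, in log2 units. Endosperm arrays lie to the right, with 71.9 for endosperm at 3 DAF replicate 2 and 148 for replicate 1.

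At 3 DAF, MFT2 stood at 18430 ± 11700 (SD, n = 2) in embryo and 73.2 ± 90.7 in endosperm (log2 fold change 8.20, SE 0.903, adjusted p = 0.00023). The lectin gene Agglutinin (6.99), the trypsin inhibitor gene OSE727A (6.92), the homeobox gene WOX6 (6.74) and CASPL2B1 (6.73) were also higher in embryo. Endosperm had the higher levels of MADS27 (853.7 ± 88.7 against 13.8 ± 15.9, log2 fold change -5.22), the nicotianamine synthase gene NAS1 (3010 ± 462 against 81.2 ± 24.7), TPP3 (-4.88) and PP2C29 (-4.50). Among named genes the largest change toward endosperm was that of RA17 (-5.36, adjusted p = 0.0117). Its call ended without embryo at 3 DAF replicate 1 (adjusted p = 0.109), without endosperm at 3 DAF replicate 1 (0.108) and with no pseudocount (0.0613).

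At 3 DAF AGPS2, a small subunit of ADP-glucose pyrophosphorylase, stood at 37620 ± 13600 (SD, n = 2) in endosperm against 4323 ± 331 in embryo (log2 fold change -3.07, SE 0.451, adjusted p = 0.00102). Of 7 starch genes 4 were lower in embryo, 0 higher and 3 not called, or 5 lower when adjusted over the list alone (median -2.09; list test adjusted p = 0.00807, and 0.683 with an estimated correlation). The calls of ALK and SSI ended without endosperm at 3 DAF replicate 1. That of ALK also ended without embryo at 3 DAF replicate 1, and that of SSI without embryo at 3 DAF replicate 2. Wx, the granule-bound starch synthase gene, had a change of -3.37 (SE 1.09) without a call (adjusted p = 0.0599). It stood at 2506 and 4414 in embryo against 40340 and 29380 in endosperm. The SE also draws on the ovary arrays, where Wx stood at 68 and 2428. Wx was called in a fit of only the compared groups (adjusted p = 0.0109) and with the median as pseudocount (0.0145), among other settings. The sucrose synthase genes SUS2 (-3.42) and SUS4 (-2.83) and the sucrose exporter gene SWEET11 (-2.99) were lower in embryo, and SWEET1a (5.63) was higher. Of 27 sucrose genes 5 were higher, 4 lower and 18 not called, or 5 higher and 7 lower adjusted over the list alone. The median of that list was -0.23, the mean 0.04 and the test downward (adjusted p = 0.463, and 0.879 with an estimated correlation); its median was 0.82 after scaling to hybridization controls. GLUA1 (-3.08) and GLUA3 (-2.74) were among 5 of 7 storage protein genes lower in embryo, with 2 not called and 6 lower when adjusted over the list alone (median -2.04; adjusted p = 0.000699, and 0.683 with an estimated correlation). The calls of GluC and GluA2 ended without endosperm at 3 DAF replicate 1, and that of GluC also without embryo at 3 DAF replicate 1. GluC also had none with no pseudocount (adjusted p = 0.112), and GluA2 none scaled to hybridization controls (0.167).

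At 3 DAF the dehydrin-type gene rab25 stood at 13440 ± 3430 (SD, n = 2) in embryo against 123.2 ± 19.2 in endosperm (log2 fold change 6.62, SE 0.584, adjusted p = 9.1e-05). It was 1 of 6 late embryogenesis genes higher in embryo, with 0 lower and 2 not called, and 6 higher adjusted over the list alone (median 4.03; adjusted p = 0.00072, and 0.683 with an estimated correlation). Without embryo at 3 DAF replicate 2 the calls of RAB16A, RAB16B, LEA3 and Em ended. Without endosperm at 3 DAF replicate 1 those of RAB16A, LEA3 and Em ended. RAB16A also had no call with no pseudocount (adjusted p = 0.091). OSH1 (6.24), WOX6 (6.74) and WOX10 (5.31) were among 9 of 17 patterning genes higher, with 0 lower, 8 not called and 10 higher adjusted over the list alone (median 1.76; adjusted p = 0.000101, and 0.626 with an estimated correlation). Of 16 cell cycle genes 5 were higher, among them CYCB1-1 (3.45), with 11 not called and 7 higher adjusted over the list alone (median 0.96; adjusted p = 0.00375, and 0.723 with an estimated correlation). The calls of CYCB2;2 and CYCA2-1 ended without either embryo array of 3 DAF and with no pseudocount (adjusted p = 0.0547 and 0.202). Of 55 auxin genes 18 were higher, including IAA7 (4.86), IAA3 (4.62) and IAA31 (4.61), 1 was lower and 36 were not called. Adjusted over the list alone, 24 auxin genes were higher and 2 lower (median 1.12; adjusted p = 0.000637, and 0.683 with an estimated correlation).

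The centromeric histone gene CenH3 (2.27, SE 0.385) was the 1 histone gene of 6 that was called at 3 DAF (list median 0.70, adjusted p = 0.284, and 0.856 with an estimated correlation). PDIL1-4, a protein disulfide isomerase gene, was lower in embryo (-2.82), while the ER folding list of 14 had 1 higher, 3 lower and 10 not called (median -0.31, and 0.92 scaled to hybridization controls; adjusted p = 0.312, and 0.793 with an estimated correlation). The cytokinin genes CKX11 (5.20) and LOGL10 (3.74) were higher in embryo, with 4 of 25 higher, 2 lower and 19 not called (median 0.63; adjusted p = 0.415, and 0.879 with an estimated correlation). ABA8OX2, encoding an abscisic acid hydroxylase, was lower (-3.54), the 1 called gene of 3 in its list (median -0.62, and 0.61 scaled to hybridization controls; adjusted p = 0.316, and 0.723 with an estimated correlation). HSP16.9B (3.76) and HSP18.6 (3.42) were higher and HSP24.1 (-4.36) lower, with 3 of 23 heat shock genes higher, 5 lower and 15 not called (median -0.50, and 0.53 scaled to hybridization controls; adjusted p = 0.498, and 0.879 with an estimated correlation). The expansin genes EXPB17 (4.86), EXPL4 (4.64) and EXPB7 (4.31) were higher, with 6 of 34 wall genes higher, 1 lower and 27 not called (median 0.21, and -0.08 at the 75th percentile scaling; adjusted p = 0.412, and 0.879 with an estimated correlation).

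MADS16 (2.30) was higher and MADS14 (-3.33) lower in embryo at 3 DAF, with 1 of 15 floral MADS-box genes higher, 2 lower and 12 not called (median -0.26, and 0.96 scaled to hybridization controls; adjusted p = 0.564, and 0.899 with an estimated correlation). The lipid transfer gene LTPL1 was higher (2.72), with 2 of 5 higher and 3 not called (median 2.09; adjusted p = 0.148, and 0.764 with an estimated correlation). Lists with fewer calls were photosynthesis (0 higher, 2 lower and 4 not called of 6; median -1.10, and 0.09 scaled to hybridization controls; adjusted p = 0.284, and 0.86 with an estimated correlation) and gibberellin (1 lower of 11; adjusted p = 0.747, and 0.897 with an estimated correlation). The gibberellin median was -0.03, and 0.76 scaled to hybridization controls, and its mean 0.07 against a downward test. The ribosomal list had 1 of 23 higher (median -0.33, and 0.25 after quantile normalization; adjusted p = 0.258, and 0.879 with an estimated correlation). Lists too small for a test held NF-YB1 (-3.67), the oil body gene PXG (-0.70), VP1 and TRAB1 (median 1.56) and the Polycomb gene fie (-1.25). Adjusted over the list alone, the lists of this and the preceding paragraph kept their counts, except cytokinin (4 higher, 3 lower), wall (6 higher, 2 lower), lipid transfer (3 higher), photosynthesis (3 lower) and ribosomal genes (0). The calls of NF-YB1 and of the maturation regulator VP1 (3.55) ended without embryo at 3 DAF replicate 1 (adjusted p = 0.0951 and 0.0703) and without the 2 arrays of highest 3' to 5' ratio (0.102 and 0.0772). They also ended without endosperm at 3 DAF replicate 2 for NF-YB1 (0.0817), and without endosperm at 3 DAF replicate 1 (0.16) or embryo at 3 DAF replicate 2 (0.0723) for VP1.

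Between embryo and endosperm at 3 DAF, 3435 genes were called by their brightest probe set (2234 higher, 1201 lower in embryo). In all, 5800 probe sets were called, 3472 higher and 2328 lower. Each call named above, other than those said to end without an array, was kept with any 1 of the 14 arrays left out. The count was 3522 and 3348 without embryo at 3 DAF replicates 1 and 2, 2402 without endosperm at 3 DAF replicate 1, and 4073 without the 2 arrays of highest 3' to 5' ratio. It was 3566 in a fit of only the compared groups and 12283 scaled to hybridization controls. The median probe set moved to -0.29 at the 75th percentile scaling and to 1.02 scaled to hybridization controls, and the share of calls that were higher in embryo was 46.2% and 92.99% there, against 59.9%.

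At 9 DAF, MFT2 again had the largest fold change toward embryo among named genes (29440 ± 1940 against 209.8 ± 105, SD, n = 2; log2 fold change 7.14, SE 0.903, adjusted p = 0.00031). NAR2.2 (7.13), pinA (7.09), G1L2 (6.99) and OC-X (6.95) followed. Endosperm had the higher levels of the aquaporin gene PIP2;5 (3357 ± 2660 against 5.40 ± 3.25, log2 fold change -7.34), BC1L6 (-5.45), MIF1 (-5.42), CASPL1B1 (-5.25) and MADS29 (-5.20, 3724 ± 1620 against 92.5 ± 54.9). NF-YB1, a transcription factor gene of the endosperm, stood at 25060 ± 9240 against 723 ± 1.63 (-5.04, SE 0.824, adjusted p = 0.00142), and the oil body gene PXG was also lower in embryo (-4.51).

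At 9 DAF AGPS2 stood at 48130 ± 2760 (SD, n = 2) in endosperm against 5660 ± 218 in embryo (log2 fold change -3.09, SE 0.451, adjusted p = 0.000718), SUS2 at 40240 ± 4670 against 1932 ± 319 (-4.38), and SWEET11 (-3.94) and SWEET15 (-2.75) were lower in embryo as well. SWEET1a was higher in embryo (5.79). Of 7 starch genes 5 were lower, 0 higher and 2 not called, or 5 lower and 1 higher adjusted over the list alone (median -1.91; adjusted p = 0.0109, and 0.683 with an estimated correlation). Wx was lower (-4.23, adjusted p = 0.0168), at 2099 and 2460 in embryo against 40800 and 44800 in endosperm. Its call ended with each of the 4 compared arrays left out, where its change ran from -4.34 to -4.11. Of 27 sucrose genes 7 were lower, 3 higher and 17 not called, or 10 lower and 3 higher adjusted over the list alone (median -1.06, and 0.17 scaled to hybridization controls; adjusted p = 0.031, and 0.683 with an estimated correlation). The sucrose list did not pass after quantile normalization (0.0652), at the 75th percentile scaling (0.0743), with the filter at the 75th percentile (0.0539), or without embryo replicate 2 (0.0909) or endosperm replicate 1 (0.0605) of that day.

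Storage protein genes at 9 DAF stood at high levels in both tissues, with GLUA1 at 14900 ± 151 in embryo and 61630 ± 2470 in endosperm (SD, n = 2; log2 fold change -2.05, SE 0.410, adjusted p = 0.00448). Its call ended with no pseudocount (adjusted p = 0.0523) and scaled to hybridization controls (0.156). Under the latter scaling the calls of GluC (0.105), GLUA3 (0.167) and GluA2 (0.766) ended too. The calls of GluC, GLUA3 and GluA2 also ended without embryo at 9 DAF replicate 1. Of 7 storage genes 5 were lower in embryo, 1 higher and 1 not called, the same when adjusted over the list alone (median -1.44; adjusted p = 0.0249, and 0.772 with an estimated correlation). The list did not pass with no pseudocount (0.074), after quantile normalization (0.197) or without embryo at 9 DAF replicate 2 (0.0538). The same embryo arrays held Wx at 2099 and 2460 and NF-YB1 at 721.8 and 724.1. Endosperm tissue in the embryo samples of 9 DAF was not tested. The chaperone gene BIP1 was lower in embryo (-2.22, adjusted p = 0.00356, and 0.089 scaled to hybridization controls). The ER folding list had 3 of 14 higher, 2 lower and 9 not called, or 4 higher and 2 lower adjusted over the list alone (median 0.36; adjusted p = 0.997, and 0.998 with an estimated correlation).

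Cell cycle genes gave the lowest list p at 9 DAF. CYCB2;2 stood at 1734 ± 449 (SD, n = 2) in embryo and 11.4 ± 13.4 in endosperm (log2 fold change 6.33, SE 0.981, adjusted p = 0.00101), with CYCA2-1 (5.04) and CycB2;1 (4.95) also higher. Of 16 cell cycle genes 14 were higher in embryo, 0 lower and 2 not called, the same adjusted over the list alone (median 3.17; adjusted p = 1.9e-06, and 0.683 with an estimated correlation). OSH1 (6.66), OSH71 (6.53) and WOX6 (5.52) were among 8 of 17 patterning genes higher, with 0 lower and 9 not called, and 8 higher adjusted over the list alone (median 1.04; adjusted p = 0.00231, and 0.683 with an estimated correlation). IAA31 (5.42), IAA30 (5.20) and IAA24 (5.05) were among 18 of 55 auxin genes higher, with 1 lower and 36 not called, or 22 higher and 4 lower adjusted over the list alone (median 1.04; adjusted p = 0.00475, and 0.683 with an estimated correlation). The cytokinin genes LOGL1 (5.20), LOGL10 (3.55) and CKX11 (3.53) were higher and RR6 (-4.38) lower, while their list of 25 had 4 higher, 3 lower and 18 not called, or 7 higher and 4 lower adjusted over the list alone (median 0.49; adjusted p = 0.565, and 0.879 with an estimated correlation).

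Of the late embryogenesis genes, 3 were called at 9 DAF. RAB16B stood at 18350 ± 936 (SD, n = 2) against 215.6 ± 35.7 (log2 fold change 6.34, SE 1.18, adjusted p = 0.00293) and RAB16C was also higher in embryo (3.81). RAB16A (0.52), LEA3 (0.66) and Em (0.95) had no call. Of 8 genes 3 were higher, 0 lower and 5 not called, or 4 higher adjusted over the list alone (median 1.23; adjusted p = 0.0482, and 0.723 with an estimated correlation). That test did not pass without embryo at 9 DAF replicates 1 (adjusted p = 0.0804) or 2 (0.0538), endosperm at 9 DAF replicate 2 (0.125), either endosperm array of 3 DAF (0.0606 and 0.0538) or 16 DAF (0.064 and 0.0627), or scaled to hybridization controls (0.143). It also failed with no pseudocount and with the filter at the 75th percentile (0.0709 each), and without the 2 arrays of highest 3' to 5' ratio (0.0613). The floral MADS-box genes were chosen as markers of ovary and maternal tissue, and such tissue in the endosperm samples of 9 DAF was not tested. MADS8 (-4.64) and MADS7 (-3.77) joined MADS29 among 6 of 15 floral MADS-box genes lower in embryo, with 1 higher and 8 not called, or 9 lower and 1 higher adjusted over the list alone. That list passed (median -1.94; adjusted p = 0.0249, and 0.793 with an estimated correlation) but not without endosperm at 9 DAF replicate 1 (0.0504). LTP110-A (3.48), LTPL1 (2.94), HSP16.9B (3.71), HSP18.6 (3.59), EXPL4 (5.86), EXPB8 (5.46) and EXPB17 (5.23) were higher in embryo, and HSP22.3 (-4.13) and EXP2 (-4.61) lower. Lipid transfer genes had 2 of 5 higher and 3 not called, the same adjusted over the list alone (median 0.20, and -0.18 at the 75th percentile scaling; adjusted p = 0.43, and 0.879 with an estimated correlation). Heat shock genes had 3 of 23 higher, 1 lower and 19 not called, the same adjusted over the list alone (median -0.50, and 0.65 scaled to hybridization controls; adjusted p = 0.805, and 0.964 with an estimated correlation). Wall genes had 9 of 34 higher, 4 lower and 21 not called, or 9 higher and 6 lower adjusted over the list alone (median 0.02, and -0.25 at the 75th percentile scaling; adjusted p = 0.815, and 0.953 with an estimated correlation).

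Between embryo and endosperm at 9 DAF, 4568 genes were called by their brightest probe set (2665 higher, 1903 lower in embryo). Called probe sets numbered 8478, with 4738 higher and 3740 lower. The count was 4255 and 4835 without embryo at 9 DAF replicates 1 and 2, 5505 and 4207 without endosperm at 9 DAF replicates 1 and 2, and 14535 scaled to hybridization controls. The median probe set moved to -0.33 at the 75th percentile scaling and 1.07 scaled to hybridization controls, and the share higher in embryo was 40.2% and 91.1% there, against 55.9%. Apart from Wx, GluC, GLUA3 and GluA2, each call of a gene named for 9 DAF was kept with any 1 array left out.

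**Figure D2:**
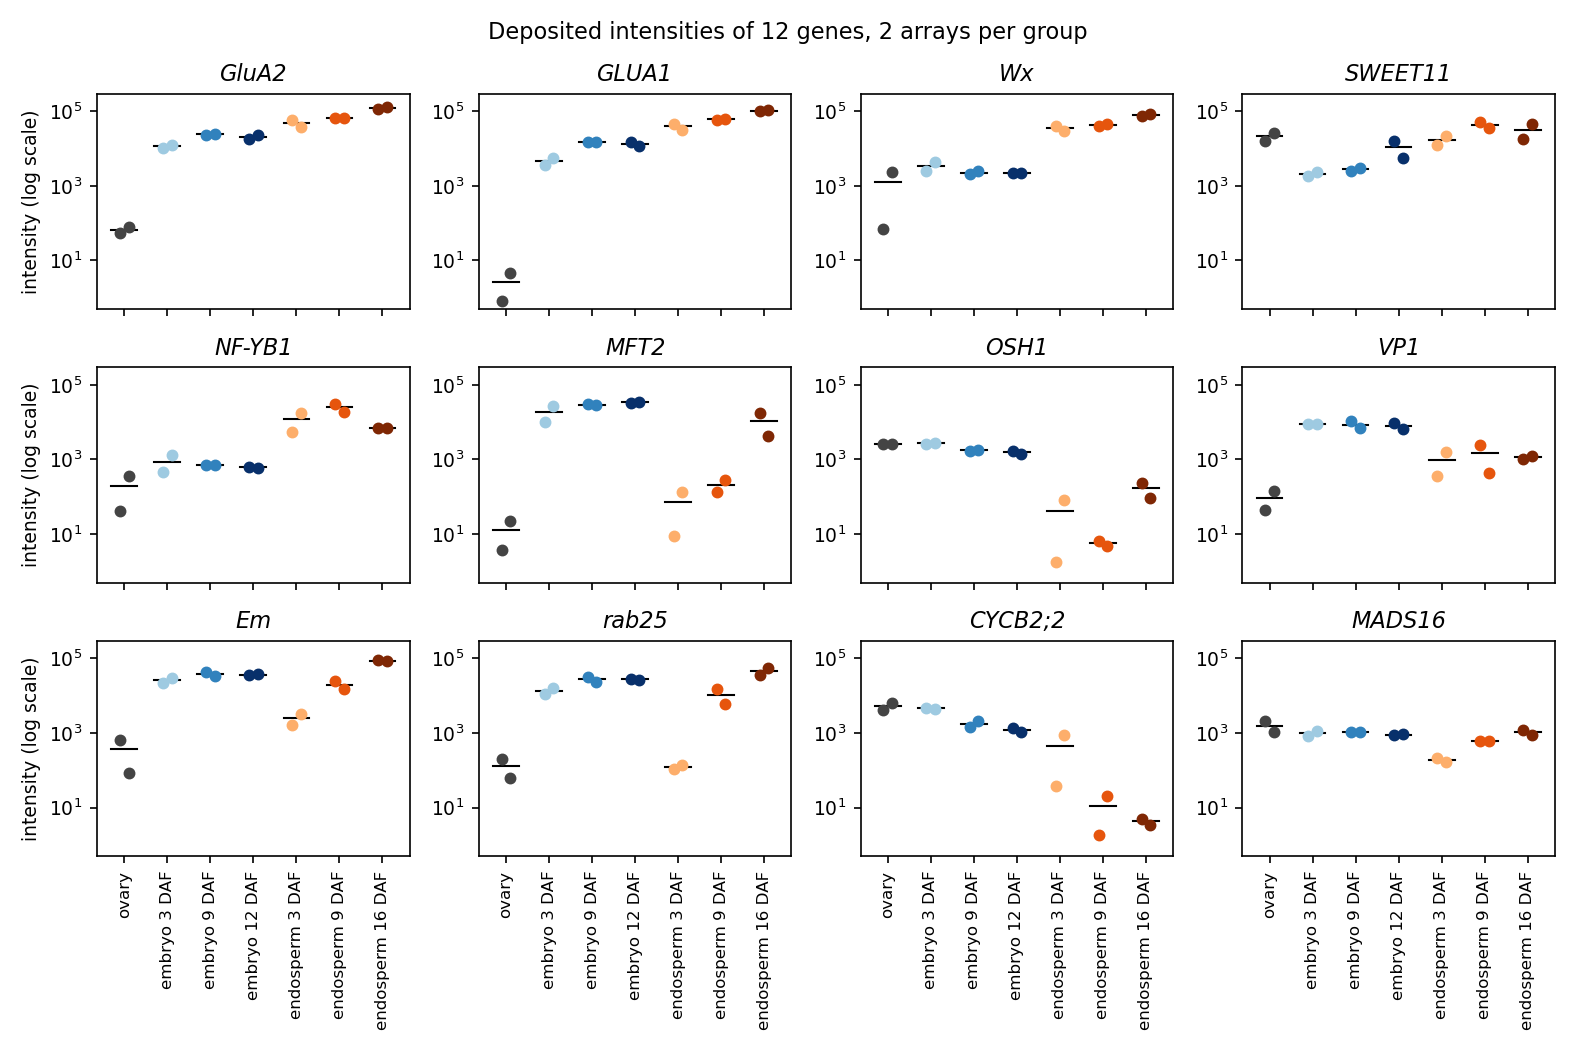
Deposited intensity (log scale) of 12 genes in the 7 groups; points are arrays (2 per group) and bars are means. GluA2 reaches 123200 in endosperm at 16 DAF, CYCB2;2 is 11.4 in endosperm at 9 DAF against 1734 in embryo, and MFT2 in endosperm at 16 DAF is 17690 and 4255 on its 2 arrays.

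From 3 to 9 DAF in embryo, the late embryogenesis gene RAB16D rose from 58.4 ± 63.5 to 1177 ± 268 (SD, n = 2; log2 fold change 4.44, SE 0.637, adjusted p = 0.0106). HSP26.7 (4.32), CPDK2 (3.78) and RNAH (2.89) also rose, and RR41 (-3.80), the homeobox gene WOX10 (-2.62) and CRK6 (-2.14) fell. VP1 stood at 9169 ± 16.2 and 8643 ± 2580 (log2 fold change -0.12) and OSH1 at 2697 ± 130 and 1767 ± 51.0 (-0.61), neither of them called. The RAB16D call ended without embryo at 9 DAF replicate 1 (adjusted p = 0.11) or 2 (0.138). The other 6 ended with each of the 4 compared arrays left out, with adjusted p from 0.064 to 0.392, and those of CPDK2, RNAH, RR41 and CRK6 also without an ovary array (0.0508 to 0.0762). All 7 ended in a fit of only the compared groups (0.0513 to 0.117). All but CRK6 ended with no pseudocount (0.0707 to 0.131).

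Storage protein genes tended upward as a list from 3 to 9 DAF in embryo with 0 of 7 called and 1 higher adjusted over the list alone (median 1.02; adjusted p = 8.31e-05, and 0.683 with an estimated correlation). GluA2 went from 11490 to 24300 (1.09, adjusted p = 0.318). Endosperm tissue in the embryo samples was not tested for this list. Late embryogenesis genes had 1 of 8 higher and 7 not called, or 2 higher adjusted over the list alone (median 0.97; adjusted p = 0.00475, and 0.683 with an estimated correlation). Heat shock genes had 1 of 23 higher, or 2 adjusted over the list alone (median 0.60; adjusted p = 0.00188, and 0.683 with an estimated correlation). Cell cycle genes had 0 of 16 called and 0 adjusted over the list alone (median -0.86; adjusted p = 0.00172, and 0.683 with an estimated correlation), with CYCB2;2 at -1.43 and PCNA at -1.13. Floral MADS-box genes had 0 of 15 called and 0 adjusted over the list alone (median -0.47; adjusted p = 0.0445, and 0.804 with an estimated correlation). Without embryo at 3 DAF replicate 1 none of storage (0.0563), late embryogenesis (0.0535), heat shock (0.292) and cell cycle (0.137) passed. Heat shock also failed without embryo at 9 DAF replicate 1 (0.133). The MADS-box list failed without embryo at 3 DAF replicate 2 (0.984), either embryo array at 9 DAF (0.128 and 0.0538) or either ovary array (0.0536 and 0.0525). It also failed with the mean of all probe sets (0.0513), no pseudocount (0.0552), quantile normalization (0.0542), the 75th percentile scaling (0.0612) and scaling to hybridization controls (0.0904). Without the 2 arrays of highest 3' to 5' ratio the storage (0.0786), late embryogenesis (0.0841), heat shock (0.351) and cell cycle (0.113) tests did not pass.

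In embryo from 3 to 9 DAF, 51 genes were called by their brightest probe set (32 higher, 19 lower). Probe sets that carry a gene made up 134 of the higher and 23 of the lower calls. Called probe sets numbered 271 in all, 243 higher and 28 lower. The count was 14 without embryo at 3 DAF replicate 1, which has the actin ratio of 1388, and 25 without the 2 arrays of highest 3' to 5' ratio. It was 3 and 7 without embryo at 9 DAF replicates 1 and 2, 168 without either ovary array and 493 without either endosperm array of 16 DAF. Without embryo at 3 DAF replicate 2 the count did not fall. It was 49 with no pseudocount and 714 with the median as pseudocount. Quantile normalization gave 147, and a fit of only the compared groups gave 73. Scaled to hybridization controls the median probe set was -0.32 and 63.6% of calls were higher, against 89.7%.

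In embryo at 9 and 12 DAF, Em stood at 37820 ± 6490 and 37060 ± 2680 (SD, n = 2), LEA3 at 20670 and 21440 (log2 fold change 0.07, SE 0.505), GluA2 at 24300 and 20780 (-0.24) and OSH1 at 1767 and 1551 (-0.19). MADS29 went from 92.5 ± 54.9 to 387.6 ± 287 without a call (1.83, SE 0.912). limma called 0 probe sets at an adjusted p under 0.05, with 1095 at an unadjusted p under 0.05. The count was 0 with each array left out and in each other setting run. ER folding genes had a list median of -0.29 with 0 of 14 called and 0 adjusted over the list alone (adjusted p = 0.0149, and 0.683 with an estimated correlation). That test did not pass without embryo at 9 DAF replicate 1 (0.289) or embryo at 12 DAF replicate 2 (0.107).

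From 3 to 9 DAF in endosperm, the kinase gene CPK12 rose from 16.6 ± 17.2 to 2848 ± 538 (SD, n = 2; log2 fold change 6.77, SE 0.727, adjusted p = 0.00142). rab25 rose from 123.2 ± 19.2 to 10610 ± 6520 (6.15, SE 0.584, adjusted p = 0.00101), and CPDK2 (5.79), CASPL1B1 (4.74) and PXG (4.50) rose as well. CIPK25 fell from 649 ± 133 to 19.8 ± 9.69 (-4.40), and with it the replication genes MCM4 (-3.64), MCM3 (-3.38), MCM2 (-3.12) and RPA32 (-3.32). The heat shock gene hsp17.9 rose from 2278 ± 403 to 23240 ± 2290 (3.35). Wx stood at 34860 ± 7750 and 42800 ± 2830 (0.31) and GluA2 at 47890 ± 12700 and 66040 ± 709 (0.49), neither called. Each of these calls ended in a fit of only the compared groups (adjusted p from 0.101 to 0.174).

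CPK12, rab25, CPDK2, CIPK25 and hsp17.9 kept their calls with any 1 array left out. Without endosperm at 3 DAF replicate 2 the calls of CASPL1B1 (adjusted p = 0.0848), PXG (0.0698), MCM4 (0.0646), MCM3 (0.0573) and MCM2 (0.0881) ended. Without endosperm at 9 DAF replicate 1 those of CASPL1B1 (0.0763), PXG (0.0542), MCM4 (0.0775), MCM3 (0.0721), MCM2 (0.122) and RPA32 (0.0559) ended. Without endosperm at 9 DAF replicate 2 those of CASPL1B1 (0.12), PXG (0.0725) and MCM2 (0.0579) ended. CASPL1B1 also lost its call with no pseudocount (0.0972).

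Cell cycle genes fell as a list in endosperm from 3 to 9 DAF, with 8 of 16 lower, 0 higher and 8 not called, or 13 lower adjusted over the list alone (median -2.55; adjusted p = 2.89e-10, and 0.626 with an estimated correlation). All 16 were higher on endosperm at 3 DAF replicate 2 than on replicate 1, with CYCB2;2 at 883.9 against 37.2. The actin 3' to 5' ratio was 66.3 on replicate 2 and 140 on replicate 1, and its bearing on this list was not tested. Late embryogenesis genes rose as a list, with 2 of 8 higher, 0 lower and 6 not called, or 6 higher adjusted over the list alone (median 2.88; adjusted p = 2.71e-05, and 0.626 with an estimated correlation). Ribosomal protein genes had 1 of 23 lower, and 1 adjusted over the list alone (median -0.51; adjusted p = 0.00188, and 0.793 with an estimated correlation), but the list did not pass without endosperm at 3 DAF replicate 1 (0.25). ER folding genes had 0 of 14 called, or 2 lower adjusted over the list alone (median -0.70; adjusted p = 0.0258, and 0.683 with an estimated correlation). They did not pass with the filter at the 75th percentile (0.16) or without replicate 1 of endosperm at 3 DAF (0.276) or 9 DAF (0.189).

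The actin 3' to 5' ratio was 140 and 66.3 on the endosperm arrays of 3 DAF and 25.9 and 20.7 on those of 9 DAF. None of these is among the 2 arrays of highest ratio, and loss of signal from the 5' end was not tested for this step. In endosperm from 3 to 9 DAF, 336 genes were called by their brightest probe set (202 higher, 134 lower). The called probe sets were 542, of which 349 were higher and 193 lower. The count was 326 and 154 without endosperm at 3 DAF replicates 1 and 2, and 97 and 126 without endosperm at 9 DAF replicates 1 and 2. In a fit of only the compared groups limma called 0. The count was 1069 with the median as pseudocount, 1033 with the filter at the 75th percentile and 979 with a variance trend. Scaled to hybridization controls the median probe set was -0.28 and 36.8% of calls were higher, against 64.4%.

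From 9 to 16 DAF in endosperm, OSE727A rose from 537.4 ± 62.9 to 45200 ± 11900 (SD, n = 2; log2 fold change 6.34, SE 0.746, adjusted p = 0.00319) and Agglutinin from 385.7 ± 56.0 to 27460 ± 16800 (5.97). OC-X (6.28), RAB16B (6.67) and MFT2 (5.38, SE 0.903) rose with them, and these 3 had stood higher in embryo than in endosperm at 9 DAF. Over 159 genes high in embryo the median log2 change was 1.99, or 0.837 scaled to hybridization controls, and the median ratio to embryo at 12 DAF was 0.0867. Embryo tissue at 16 DAF is not excluded. RAB16C (3.81), the cytokinin gene LOGL1 (3.45) and the cellulose synthase gene CESA4 (4.09, from 902.4 ± 198 to 15410 ± 1780) also rose. The named genes with the largest falls were PIP2;5 (-4.80), the expansin gene EXPB3 (-4.51), AGO14 (-3.56), GST-I (-3.34) and RR41 (-3.34). GluA2 went from 66040 ± 709 to 123200 ± 10200 (0.90, adjusted p = 0.213), Wx from 42800 to 79460 (0.89) and MADS29 from 3724 ± 1620 to 384.5 ± 365 (-3.56, adjusted p = 0.0509), none of them called. The changes of GluA2 and Wx were -0.31 and -0.32 scaled to hybridization controls. The brightest value was 78630 and 78150 on the arrays of 9 DAF and 151800 and 175700 on those of 16 DAF.

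OSE727A, OC-X, Agglutinin, RAB16C, LOGL1 and CESA4 kept their calls with any 1 array left out, and each call named for this step ended in a fit of only the compared groups (adjusted p from 0.159 to 0.204). Without the 2 arrays of highest 3' to 5' ratio the calls of RAB16C (0.0523), RAB16B (0.0818), EXPB3 (0.0631), AGO14 (0.136), GST-I (0.12) and RR41 (0.117) ended. The calls of RAB16B and MFT2 ended without endosperm at 9 DAF replicate 1 (adjusted p = 0.06 and 0.0675) or 2 (0.0857 and 0.0611), and that of RAB16B without endosperm at 16 DAF replicate 2 (0.0587). EXPB3 ended without endosperm at 9 DAF replicate 1 (0.0613). PIP2;5, AGO14, GST-I and RR41 ended in at least 3 of the 4 fits that leave out a compared array (0.0678 to 0.218), PIP2;5 also without an embryo array of 9 or 12 DAF (0.0508 to 0.0535). With no pseudocount MFT2 (0.0636), PIP2;5 (0.109) and GST-I (0.0868) had no call, and with the median as pseudocount RR41 had none (0.0588).

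Late embryogenesis genes had 2 of 8 higher, 0 lower and 6 not called from 9 to 16 DAF, or 5 higher adjusted over the list alone (median 2.03; adjusted p = 0.000362, and 0.683 with an estimated correlation). Patterning genes had 3 of 17 higher, 0 lower and 14 not called, or 4 higher and 1 lower adjusted over the list alone (median 1.14; adjusted p = 0.0249, and 0.683 with an estimated correlation). OSH1 stood at 5.65 ± 1.06 at 9 DAF and 167.7 ± 102 at 16 DAF, against 1551 ± 183 in embryo at 12 DAF. Embryo tissue in the samples of 16 DAF is not excluded for these genes. The patterning test did not pass after quantile normalization (0.0603) or without endosperm at 16 DAF replicate 1 (0.064). Floral MADS-box genes had 0 of 15 called, or 6 lower adjusted over the list alone (median -1.10; adjusted p = 0.0342, and 0.793 with an estimated correlation). They did not pass without endosperm at 16 DAF replicate 1 (0.392) or endosperm at 9 DAF replicate 1 (0.108), scaled to hybridization controls (0.177), with no pseudocount (0.0552) or with the mean of all probe sets (0.0522). Auxin genes had 6 of 55 higher, 2 lower and 47 not called, or 17 higher and 6 lower adjusted over the list alone (median 0.52, and -0.54 scaled to hybridization controls; adjusted p = 0.0482, and 0.793 with an estimated correlation). The auxin test did not pass without endosperm at 9 DAF replicate 2 (0.233) or endosperm at 16 DAF replicates 1 (0.0893) and 2 (0.107), nor without the 2 arrays of highest 3' to 5' ratio (0.0952). It also failed in 8 other settings (0.0503 to 0.0855), among them embryo at 9 DAF replicate 1 left out (0.051) and either embryo array of 12 DAF left out (0.0515 and 0.0537).

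In endosperm from 9 to 16 DAF, 822 genes were called by their brightest probe set (535 higher, 287 lower). In all, 1626 probe sets were called, 1064 higher and 562 lower. The count was 2550 and 389 without endosperm at 16 DAF replicates 1 and 2, of which replicate 2 has the actin ratio of 948, 326 and 115 without endosperm at 9 DAF replicates 1 and 2, and 260 without the 2 arrays of highest 3' to 5' ratio. It was 761 with no pseudocount, 2783 with the median as pseudocount, 0 in a limma fit of only the compared groups, and 6631 scaled to hybridization controls. The median probe set was 0.13 at the 75th percentile scaling and -0.87 scaled to hybridization controls. The share of calls that rose was 54.6% after quantile normalization and 2.97% scaled to hybridization controls (12660 and 16610 at 16 DAF), against 65.4%; 759 of the 1626 calls were kept in the latter.

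**Figure D3:**
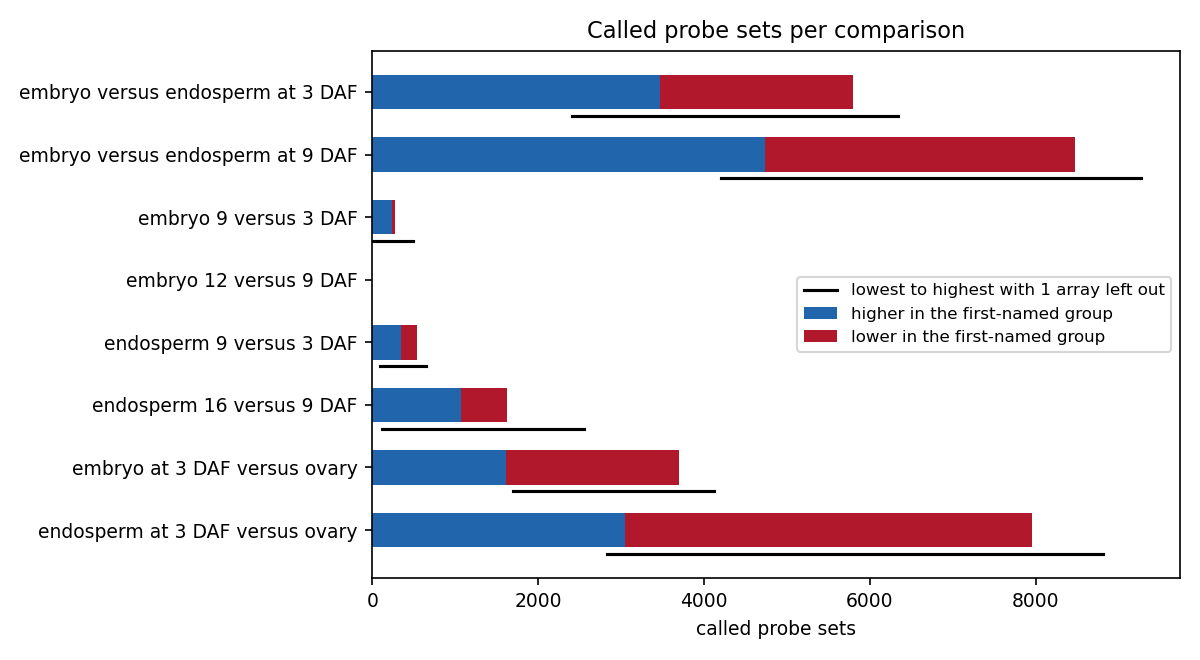
Probe sets called higher (blue) and lower (red) in the 8 comparisons; black lines give the range of the total with each of the 14 arrays left out. The total is 8478 (4207 to 9272) for embryo against endosperm at 9 DAF and 0 for embryo at 12 against 9 DAF.

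The change from 3 to 9 DAF was larger in endosperm than in embryo for rab25, which went from 13440 ± 3430 to 27560 ± 5890 (SD, n = 2) in embryo and from 123.2 ± 19.2 to 10610 ± 6520 in endosperm (log2 difference -5.11, SE 0.826, adjusted p = 0.0497). That call ended in nearly every alternative, with adjusted p up to 0.2 when embryo at 9 DAF replicate 2 was left out and 0.108 in a fit of only the compared groups. In the interaction 13 genes were called by their brightest probe set, all lower, and rab25 is the 1 with a name. In all, 43 probe sets were called, 16 higher and 27 lower, of which 7 and 16 carry a gene. The count ran from 0 to 28 with each array left out and was 0 in 8 of those fits. It was 0 with no pseudocount and in a fit of only the compared groups, 1 without the 2 arrays of highest 3' to 5' ratio, 10 at the 75th percentile scaling and with no filter, 22 after quantile normalization, and 27 scaled to hybridization controls. It was 235 with the median as pseudocount, 119 with the filter at the 75th percentile and 127 with a variance trend. The share of higher calls was 37.2%, and 50% and 55.6% at the 75th percentile scaling and scaled to hybridization controls.

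Cell cycle genes gave the strongest list result of the interaction, since they fell further in endosperm than in embryo (median 1.55, 0 of 16 called, 4 higher adjusted over the list alone; adjusted p = 1.9e-06, and 0.683 with an estimated correlation). Late embryogenesis genes rose further in endosperm (median -1.17, 1 of 8 lower, and 1 adjusted over the list alone; adjusted p = 0.0245, and 0.683 with an estimated correlation). With 0 genes called and 0 adjusted over the list alone, the tests also passed for floral MADS-box genes (median -1.68; adjusted p = 0.00621, and 0.772 with an estimated correlation), sucrose genes (-0.72; 0.0249, and 0.683 with an estimated correlation), storage genes (0.60; 0.0249, and 0.772 with an estimated correlation) and ribosomal genes (0.43; 0.0067, and 0.81 with an estimated correlation). Without embryo at 3 DAF replicate 1 the late embryogenesis (0.054), storage (0.43) and ribosomal (0.514) tests did not pass, and without replicate 2 the late embryogenesis (0.073), sucrose (0.656) and MADS-box (0.277) tests did not. Without endosperm at 3 DAF replicate 1 the storage (0.311), ribosomal (0.393) and MADS-box (0.0683) tests did not pass, and without replicate 2 the late embryogenesis (0.121) and sucrose (0.0607) tests did not. Without replicate 1 of embryo at 9 DAF the storage (0.0839) and ribosomal (0.113) tests did not pass. Without replicate 1 of endosperm at 9 DAF the storage (0.0676), ribosomal (0.0703) and late embryogenesis (0.0544) tests did not pass. Sucrose failed without embryo at 9 DAF replicate 2 (0.147) and after quantile normalization (0.0895), as did ribosomal genes after it (0.0603), and storage failed with no pseudocount (0.071). Without the 2 arrays of highest 3' to 5' ratio the ribosomal (0.474), storage (0.451) and late embryogenesis (0.0786) tests did not pass.

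Against ovary, embryo at 3 DAF had far higher levels of the amylase gene AMY1.4 (20740 ± 8850 against 6.85 ± 4.88, SD, n = 2; log2 fold change 10.06, SE 0.787, adjusted p = 2.03e-05). A prolamin gene (9.87), MFT2 (9.47), ETR4 (8.83) and Agglutinin (8.76) followed. ASP1, encoding a transcriptional corepressor, was lower (61.2 ± 22.1 against 14340 ± 2600, -7.64), as were JAZ9 (-6.70), BGLU27 (-6.37), AGO18 (-5.99) and FDRMADS2 (-5.81). VP1 stood at 9169 ± 16.2 against 92.1 ± 69.6 (6.64, SE 0.840, adjusted p = 0.000576), WOX10 at 2452 ± 613 against 4.60 ± 1.84, and WOX6 (6.51) and WOX11 (4.77) were higher too. OSH1 (0.07), CYCB2;2 (-0.19) and PCNA (0.09) were not called.

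Storage protein transcripts were higher in the embryo samples of 3 DAF than in ovary, with GluB5 (8.71), GLUA1 (8.29) and GluA2 (7.21, 11490 ± 1820 against 66.2 ± 16.2, SD, n = 2) among 6 of 7 genes higher, 0 lower and 1 not called. Adjusted over the list alone, 6 were higher (median 7.49; adjusted p = 1.63e-11, and 0.626 with an estimated correlation). The same embryo arrays held Wx at 3460 ± 1350 and NF-YB1 at 876.4 ± 574, or 9.92% and 7.39% of endosperm at 3 DAF, with GLUA1 at 11.9%, AGPS2 at 11.5% and GluA2 at 24.0% of it. Endosperm tissue in those samples was not tested. Of 8 late embryogenesis genes 5 were higher, including rab25 (6.73), Em (6.63) and LEA3 (3.93), with 0 lower and 3 not called, or 6 higher and 1 lower adjusted over the list alone (median 4.30; adjusted p = 4.3e-05, and 0.626 with an estimated correlation). MADS29 (-5.74) and MADS21 (-4.42) were among 10 of 15 floral MADS-box genes lower, with 0 higher and 5 not called, or 13 lower adjusted over the list alone (median -3.34; adjusted p = 1.9e-06, and 0.683 with an estimated correlation). LTP-2 (6.02) was among 2 of 5 lipid transfer genes higher, with 3 not called and 2 higher adjusted over the list alone (median 1.56; adjusted p = 0.0221, and 0.683 with an estimated correlation). That list did not pass without embryo at 3 DAF replicate 2 (0.101). The light-harvesting gene LHCP at LOC4324599 (-3.53) was among 3 of 6 photosynthesis genes lower, with 3 not called and 3 lower adjusted over the list alone (median -2.05; adjusted p = 0.045, and 0.723 with an estimated correlation). That list did not pass without ovary replicate 2 (0.166), embryo at 3 DAF replicate 1 (0.172) or endosperm at 9 DAF replicate 1 (0.0549), after quantile normalization (0.0603), with no filter (0.0599), with no pseudocount (0.0534) or without the 2 arrays of highest 3' to 5' ratio (0.168).

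The sugar transporter genes SWEET5 (-4.89) and SWEET11 (-3.31) were lower and SWEET1a (3.43) higher in embryo at 3 DAF than in ovary. Of 27 sucrose genes 1 was higher, 5 were lower and 21 not called, or 2 higher and 5 lower adjusted over the list alone (median -0.34, and 0.48 scaled to hybridization controls; adjusted p = 0.694, and 0.897 with an estimated correlation). The cytokinin genes RR9 (-4.27), RR6 (-3.76) and CKX5 (-3.75) were lower. Of 25 cytokinin genes 1 was higher, 6 were lower and 18 not called, or 1 higher and 9 lower adjusted over the list alone (median -0.93; adjusted p = 0.113, and 0.793 with an estimated correlation). The auxin genes IAA26 (3.96) and YUCCA1 (2.90) were higher and IAA14 (-3.13), IAA18 (-3.08) and ARF8 (-2.25) lower. Of 55 auxin genes 7 were higher, 5 lower and 43 not called, or 8 higher and 6 lower adjusted over the list alone, with a median of -0.17, 0.62 scaled to hybridization controls, a mean of -0.01 and an upward test (adjusted p = 0.731, and 0.953 with an estimated correlation). HSP16.9A (5.50), HSP18.6 (5.02) and HSP16.9B (4.34) were the 3 of 23 heat shock genes higher, and 3 adjusted over the list alone (median 0.38; adjusted p = 0.109, and 0.793 with an estimated correlation). EXPB9 (-4.93) and EXP32 (-3.77) were lower and EXP29 (3.22), EXPB7 (2.46) and EXPB8 (2.36) higher. Of 34 wall genes 4 were higher, 4 lower and 26 not called, or 5 higher and 4 lower adjusted over the list alone (median -0.13, and 0.56 scaled to hybridization controls; adjusted p = 0.805, and 0.953 with an estimated correlation). Patterning genes had 4 of 17 higher and 1 lower, the same adjusted over the list alone, with a median of -0.21, 0.61 scaled to hybridization controls, a mean of 0.72 and an upward test (adjusted p = 0.312, and 0.835 with an estimated correlation). The cell cycle list had 0 of 16 called and 0 adjusted over the list alone, with a median of -0.20, 0.63 scaled to hybridization controls, a mean of -0.14 and an upward test (adjusted p = 0.953, and 0.993 with an estimated correlation).

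Between embryo at 3 DAF and ovary, 2059 genes were called by their brightest probe set (903 higher, 1156 lower in embryo). Called probe sets numbered 3694, with 1615 higher and 2079 lower. The calls of SWEET1a, IAA14, IAA18, ARF8, EXP29, EXPB7 and EXPB8 ended in at least 2 of the 4 fits that leave out a compared array (adjusted p from 0.0528 to 0.226). With no pseudocount those of IAA14, ARF8, EXP29 and EXPB7 ended (0.0527 to 0.0747), and in a fit of only the compared groups those of EXP29 (0.0876) and EXPB8 (0.0833). IAA14 and ARF8 also lost theirs scaled to hybridization controls (0.0531 and 0.177), and IAA14, EXP29 and EXPB7 without the 2 arrays of highest 3' to 5' ratio (0.105, 0.0518 and 0.0919). Each other gene called and named for this comparison kept its call with any 1 array left out. The count was 2105 and 1723 without embryo at 3 DAF replicates 1 and 2, 1696 and 2395 without ovary replicates 1 and 2, and 2743 without the 2 arrays of highest 3' to 5' ratio. It was 2428 in a fit of only the compared groups and 6778 scaled to hybridization controls. The median probe set was 0.10 at the 75th percentile scaling and 0.69 scaled to hybridization controls, with 81.9% of calls higher in the latter against 43.7%.

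Against ovary, endosperm at 3 DAF was marked by storage protein transcripts: prolamin (50150 ± 9510 against 2.70 ± 0.849, a level below the pseudocount, SD, n = 2; log2 fold change 11.72, SE 0.405, adjusted p = 3.71e-08), GLUA1 (11.37), GLUA3 (10.22), GluC (10.18) and GluB5 (10.16). Of 7 storage genes 6 were higher, 0 lower and 1 not called, with 6 higher adjusted over the list alone (median 10.18; adjusted p = 2.48e-10, and 0.626 with an estimated correlation). Wx stood at 34860 ± 7750 against 1248 ± 1670 (6.28, SE 1.09, adjusted p = 0.00242) and AGPS2 at 37620 ± 13600 against 2568 ± 1270 (3.91). Of 7 starch genes 5 were higher, 1 lower and 1 not called, the same adjusted over the list alone (median 3.26; adjusted p = 0.00172, and 0.683 with an estimated correlation). SUS4 (4.12) was higher, and SUT5 (-4.91) and SWEET4 (-4.20) were lower. Of 27 sucrose genes 4 were higher, 7 lower and 16 not called, or 5 higher and 9 lower adjusted over the list alone, with a median of -0.05, 0.14 at the 75th percentile scaling, a mean of -0.46 and an upward test (adjusted p = 0.824, and 0.953 with an estimated correlation). NF-YB1 (6.18) was higher. The ovary arrays held Wx at 68.0 and 2428 and NF-YB1 at 41.2 and 352.4, the higher values on replicate 2, which 1 of its labels gives as 1 DAF. Without ovary replicates 1 and 2 the change of Wx was 3.82 and 8.75, and that of NF-YB1 4.79 and 7.57. PDIL1-4 (4.20) was among 3 of 14 ER folding genes higher, with 1 lower and 10 not called, or 6 higher and 1 lower adjusted over the list alone (median 0.76; adjusted p = 0.0846, and 0.683 with an estimated correlation).

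The named genes with the largest decreases from ovary to endosperm were FOR1 at LOC4343645 (46.0 ± 54.5 against 8346 ± 6510, SD, n = 2; log2 fold change -7.33), ASP1 (-6.46), mfs1 (-6.19), PNH1 (-6.19) and HAK17 (-6.18). OSH1 stood at 41.6 ± 56.2 against 2570 ± 28.4 (-6.17, SE 0.715, adjusted p = 0.000251). It and PNH1 were among 9 of 17 patterning genes lower, with 1 higher and 7 not called, or 10 lower and 1 higher adjusted over the list alone (median -2.01; adjusted p = 0.0267, and 0.683 with an estimated correlation), though not with no pseudocount (0.0534). CYCB2;2 (-4.65) and CYCB1-1 (-3.17) were among 7 of 16 cell cycle genes lower, with 0 higher and 9 not called, or 9 lower adjusted over the list alone (median -1.49; adjusted p = 0.00943, and 0.772 with an estimated correlation). MADS4 (-3.76) was among 11 of 15 floral MADS-box genes lower, with 0 higher and 4 not called, or 13 lower adjusted over the list alone (median -2.90; adjusted p = 0.00172, and 0.715 with an estimated correlation).

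Many auxin and cytokinin genes were lower in endosperm at 3 DAF than in ovary. IAA3 (980.8 ± 1070 against 19020 ± 2090, SD, n = 2; log2 fold change -4.88), ARF8 (-4.70) and IAA30 (-4.25) were among 24 of 55 auxin genes lower, with 2 higher and 29 not called, or 27 lower and 3 higher adjusted over the list alone (median -1.19; adjusted p = 0.00475, and 0.683 with an estimated correlation). CKX11 (-4.33) and LOGL3 (-4.23) were among 13 of 25 cytokinin genes lower, with 0 higher and 12 not called, or 15 lower and 1 higher adjusted over the list alone (median -2.16; adjusted p = 0.00646, and 0.683 with an estimated correlation). ABA8OX2 (3.23, adjusted p = 0.00132) was higher and ABA8OX1 (-3.38) lower, with 1 of 3 abscisic acid genes higher, 1 lower and 1 not called, the same adjusted over the list alone (median 1.17; adjusted p = 0.44, and 0.793 with an estimated correlation). HSP24.1 (4.91) and HSP16.9A (4.80) were among 4 of 23 heat shock genes higher, with 1 lower and 18 not called, or 8 higher and 3 lower adjusted over the list alone (median 0.77; adjusted p = 0.00688, and 0.683 with an estimated correlation). That test did not pass without endosperm at 3 DAF replicate 1 (0.0708). RPL27 (2.59) was among 2 of 23 ribosomal genes higher, with 21 not called and 2 higher adjusted over the list alone (median 0.51, and -0.20 after quantile normalization; adjusted p = 0.00395, and 0.793 with an estimated correlation). After quantile normalization that test did not pass (0.95), and with the mean of all its probe sets RPL27 had no call (-0.46, adjusted p = 0.314). LTP-2 (5.83) was higher and LTPL1 (-2.62) lower, with 1 of 5 lipid transfer genes higher, 1 lower and 3 not called, the same adjusted over the list alone. That list had a median of -0.42, 0.04 at the 75th percentile scaling, a mean of 0.72 and an upward test (adjusted p = 0.63, and 0.879 with an estimated correlation). EXPB17 (-4.96) and EXP32 (-4.04) were lower and EXP8 (2.61) and EXP10 (1.52) higher, with 2 of 34 wall genes higher, 7 lower and 25 not called, or 2 higher and 10 lower adjusted over the list alone (median -0.74; adjusted p = 0.177, and 0.793 with an estimated correlation).

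Between endosperm at 3 DAF and ovary, 4622 genes were called by their brightest probe set (1515 higher, 3107 lower in endosperm). The called probe sets were 7953, of which 3047 were higher and 4906 lower. The calls of ABA8OX1, EXP8 and EXP10 ended without either ovary array and without endosperm at 3 DAF replicate 1 (adjusted p from 0.0534 to 0.219). With no pseudocount those of ABA8OX1 (0.0577) and EXP8 (0.0542) ended, in a fit of only the compared groups those of EXP8 (0.0518) and EXP10 (0.0825), and scaled to hybridization controls that of EXP10 (0.0944). Each other gene called and named for this comparison kept its call with any 1 array left out. The count was 2827 without endosperm at 3 DAF replicate 1 and 3711 and 5097 without ovary replicates 1 and 2. The median probe set was 0.35 at the 75th percentile scaling and -0.36 scaled to hybridization controls. The share of higher calls was 59.0% and 23.1% there, against 38.3%.

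The storage genes GLUA1, GluB5, GluA2 and prolamin were higher, and ASP1 and EXP32 lower, in both embryo and endosperm at 3 DAF than in ovary. In all, 1930 probe sets were called the same way in both comparisons, 538 higher and 1392 lower, and 135 were called in opposite ways. Independent lists of these sizes would share 379 the same way and 358 in opposite ways. In 100 simulated sets without any change, made with shared ovary arrays, at most 1 probe set was shared. Since no probe set changes there, that count does not show how far shared ovary arrays raise the overlap of real calls. The fold changes of the comparisons correlated at 0.531, against 0.499 (0.489 to 0.509) in those sets, with a covariance of 1.11 against 0.198 (0.192 to 0.204). With embryo compared to ovary replicate 1 and endosperm to replicate 2, 868 were called the same way and 42 in opposite ways, against 117 and 106 for independent lists (correlation 0.434, covariance 0.980). The other way round these were 710 and 93, against 109 and 108 (0.355 and 0.831). The shared count was 790 without ovary replicate 1, 1105 and 1052 without embryo at 3 DAF replicates 1 and 2, 1203 without endosperm at 3 DAF replicate 1, 1226 with no pseudocount and 1196 in a fit of only the compared groups.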

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

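The tests on embryo tissue, ovary tissue, array scaling and 276 probe sets in this part were chosen only after the result was seen. The interaction, its list tests and the test on signal from the 5' end were chosen before.

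The tissue by time interaction was flagged because the change from 3 to 9 DAF differs between embryo and endosperm for 43 probe sets by limma. It was also flagged for rab25 (log2 difference -5.11) and for the list medians of sucrose genes (-0.725), storage protein genes (0.598), late embryogenesis genes (-1.167), cell cycle genes (1.554), ribosomal protein genes (0.434) and floral MADS-box genes (-1.678). None of these list tests passed with an estimated correlation (adjusted p from 0.683 to 0.81).

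Genes high in embryo rose in endosperm from 9 to 16 DAF, with a median log2 change of 1.99 over 159 genes, or 0.837 scaled to hybridization controls. Scaling of the dimmer arrays is argued against, since the rise exceeded that of 79 ovary-high genes by 1.38 (their median was 0.609). Embryo tissue in the 16 DAF samples is not excluded for most of them: their median ratio to embryo at 12 DAF was 0.0867, and 91.2% reached at least 0.25 of it. It is argued against as the source of the late embryogenesis transcripts at 16 DAF, whose median ratio over 8 genes was 1.59. Their ratios ran from 0.213 (RAB16D) and 0.798 (RAB16C) to 2.67 (RAB16A). Scaled to hybridization controls their median was 0.298, against 0.0163 for the 159 genes. Some of the 8 already stood high in endosperm at 9 DAF, such as Em (24810 and 15110) and rab25 (15220 and 5997). The 159 genes were chosen low there. The ratio therefore bears on the level at 16 DAF, not the rise. For RAB16D embryo tissue is not excluded, since 0.223 was the 90th percentile of the 159 ratios. Embryo at 16 DAF was not measured. A rise of these genes within endosperm, for which the samples hold no separate tissue, stays open beside embryo tissue.

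Probe sets higher in embryo at 9 than at 3 DAF numbered 243, and embryo at 3 DAF replicate 1 has the high 3' to 5' ratio. The total of 271 higher and lower calls was 14 without that array, and 3 and 7 without embryo at 9 DAF replicates 1 and 2. It did not fall without embryo at 3 DAF replicate 2. Loss of signal from the 5' end cannot be told apart from a developmental change. Between the endosperm arrays at 16 DAF the 243 probe sets differed by -0.315 more than all probe sets. Over 276 probe sets called higher with replicate 2 left out, embryo at 12 DAF exceeded replicate 2 by a median of 2.06, against 0.179 for probe sets matched on their level at 9 DAF. That measure was chosen after one on the 243 probe sets themselves, which their selection had fixed, and it rests on 1 array at 3 DAF, so it excludes nothing. A developmental rise and loss of signal on replicate 1 both stay open.

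Endosperm at 3 DAF replicate 2 lay closer to ovary and embryo than replicate 1. Embryo tissue is argued against, since 57 embryo-only genes gained 0.855% of the embryo level while 203 genes high in both gained 9.02%. Ovary tissue is argued against as well for 79 ovary-only genes, which gained 0.433%. They were chosen to be low in endosperm at 9 DAF, so the test leaves out ovary genes that stay high there, such as MADS29. The change of MADS29 from ovary was -3.97 with replicate 2 left out and -2.74 with both arrays. Maternal tissue with such genes was not tested. All 16 cell cycle genes were higher on replicate 2. A difference in stage or in the share of dividing cells stays open and was not tested.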

How the results depend on the processing

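With n = 2 arrays per group, signal over background limits what can be called: calls of low intensity genes depend on the pseudocount and the filter. Where an array is left out, the lone array of its group is assumed to vary like the other groups. No minimum fold change gave the same counts as reported. The 2 alternatives on hybridization controls and on 3' to 5' ratios were chosen only after the data were seen. The cause of the shifts below was not tested.

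Counts of calls are given for embryo against endosperm at 3 and 9 DAF (5800 and 8478), embryo at 9 against 3 DAF (271), endosperm at 9 against 3 and 16 against 9 DAF (542 and 1626), embryo and endosperm at 3 DAF against ovary (3694 and 7953), the shared ovary calls (1930) and the interaction (43), where they moved by more than 1.5 times. At the stricter threshold (adjusted p under 0.01, absolute log2 of at least 2) they were 2664, 3999, 44, 138, 229, 1525, 3418, 715 and 0. With no pseudocount, embryo at 9 against 3 DAF had 49, endosperm at 16 against 9 DAF 761, the shared calls 1226 and the interaction 0. With the median as pseudocount, embryo at 9 against 3 DAF had 714, endosperm at 9 against 3 and 16 against 9 DAF 1069 and 2783, and the interaction 235. Quantile normalization gave 147 for embryo at 9 against 3 DAF and 22 for the interaction, which had 10 at the 75th percentile scaling and 10 with no filter. The filter at the 75th percentile gave 1033 and a variance trend 979 for endosperm at 9 against 3 DAF, and 119 and 127 for the interaction. In fits of only the compared groups, embryo against endosperm at 3 DAF had 3566, embryo at 9 against 3 DAF 73, embryo at 3 DAF against ovary 2428, the shared calls 1196, and both endosperm steps and the interaction 0. Scaled to hybridization controls, embryo against endosperm had 12283 and 14535, endosperm at 16 against 9 DAF 6631, embryo at 3 DAF against ovary 6778 and the interaction 27. Without the 2 arrays of highest 3' to 5' ratio, embryo at 9 against 3 DAF had 25, endosperm at 16 against 9 DAF 260 and the interaction 1. With the 2 ovary arrays divided between the comparisons the shared calls were 868 and 710. Embryo at 12 against 9 DAF had 0 in every setting run.

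With each array left out the counts ran from 2402 to 6333 and 4207 to 9272 (embryo against endosperm at 3 and 9 DAF), 3 to 493 (embryo at 9 against 3 DAF), 97 to 649 and 115 to 2550 (endosperm steps), 1696 to 4116 and 2827 to 8810 (embryo and endosperm at 3 DAF against ovary), 790 to 2156 (shared calls) and 0 to 28 (interaction). The 48 list tests that passed became 0 with the estimated correlation, and 41 to 51 with each array left out. Named genes were followed in each comparison and each fit that leaves out an array. The result was the same in 5195 such entries, lost in 589, gained in 25 and reversed in 1. An entry with no call in either fit counts as the same, and many fits leave out an array that is not compared. The 5195 is therefore not a count of kept calls.

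The replicate block gave 0 for the interaction and moved no other count by more than 1.5 times. Deviations of same-numbered arrays correlated from -0.24 to 0.18 over 21 pairs of groups (median 0.002), so the arrays share only a number and the block is not a pairing.

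The direction reversed for CESA2 between embryo and endosperm at 9 DAF (1.35 with the mean of all probe sets), for RPL27 between endosperm at 3 DAF and ovary (-0.459 with the mean of all probe sets) and for RAB16A in that comparison (-2.838 without ovary replicate 2, 4.276 without replicate 1). Scaled to hybridization controls, 4328 of the 5800 calls at 3 DAF and 6026 of the 8478 at 9 DAF were kept, and 0 calls reversed.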

Other observations

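Relative to embryo at 12 DAF, endosperm at 16 DAF held, in deposited values, RAB16A at a ratio of 2.67, Em at 2.37, Dhn1 at 2.07, rab25 at 1.66, LEA3 at 1.52, RAB16B at 1.16, RAB16C at 0.798 and RAB16D at 0.213. Scaled to hybridization controls all 8 ratios were below 1, from 0.0422 (RAB16D) to 0.499 (RAB16A). RAB16A averaged 113100 ± 9320 (SD, n = 2) in endosperm at 16 DAF, 33330 ± 17600 at 9 DAF and 574.8 ± 360 at 3 DAF, against 42340 ± 7540 in embryo at 12 DAF. VP1, a regulator of seed maturation, averaged 1140 ± 177 in endosperm at 16 DAF and 7954 ± 2210 in embryo at 12 DAF. These ratios were not tested as a comparison.

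NF-YB1 averaged 196.8 ± 220 (SD, n = 2) in ovary, 11860 ± 8860, 25060 ± 9240 and 7028 ± 172 in endosperm at 3, 9 and 16 DAF, and 876.4 to 618 in embryo. MADS29 averaged 4960 ± 48.7 in ovary, 1016 ± 1010, 3724 ± 1620 and 384.5 ± 365 in endosperm at 3, 9 and 16 DAF, and 87.2, 92.5 and 387.6 in embryo at 3, 9 and 12 DAF. Probe sets of the same gene were called in opposite ways for 10 genes between embryo and endosperm at 3 DAF, 24 at 9 DAF and 22 between endosperm at 3 DAF and ovary, of 2818 genes with several probe sets. In endosperm at 9 DAF the median storage protein gene stood at 75% of the brightest value of its array. Of the 243 probe sets that rose in embryo from 3 to 9 DAF, 55.1% carry a gene, against 51.4% of all tested.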
